A study of Mus musculus with 8 samples.

How the data were processed

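Total RNA of sorted LSK cells from 8 mice was extracted with the Qiagen RNeasy Micro kit, amplified linearly with the NuGEN Ovation system, labelled with biotin and hybridised to Affymetrix Mouse Expression Array 430 2.0 arrays, per the labels' protocols. The deposited values were log2 intensities, 1 column per mouse, which the authors made with RMA (background correction, quantile normalisation and summary of probes into probe sets), the affy package and R 2.11.0, per the submitters' processing notes. The log2 scale was read from the values. A chip definition, a filter and a genome build were not given in the sources used here, and scanner files, slides and scan dates were not used here, so no other background correction, normalisation or batch could be tried. Quantile normalisation within RMA makes arrays alike in distribution, so a shift of most transcripts in one direction would not be seen.

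The table held 45101 probe sets, 64 of them controls that were left out of the tests. Probe sets were named through the platform annotation of the array, with Entrez identifiers matched to the RefSeq genes of assembly GRCm38.p6 for 34741 probe sets, of which 0 symbols changed. A single gene symbol was given for 34945 probe sets and several for 932, and 9160 were not named here. This left 18193 genes, 9010 of them with over 1 probe set, and each was represented by the probe set with the highest mean over all 8 arrays.

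Genotype was taken from the labels, with 4 arrays each. The labels describe separate mice. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, mutant minus wild type, without covariates and two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Single values were compared with two-sided exact permutation tests, whose smallest p is 0.0286 for 4 arrays against 4. Error is given as the SD over arrays or the SE of the limma change.

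Before the data were examined, 24 gene lists were fixed for signalling, lineage, cell cycle, metabolic, inflammatory, handling, sex-linked and other cell type genes. Camera tested the 23 lists with at least 5 measured members at a preset correlation of 0.01, adjusted over the lists, and the sex-linked list had 4. List members that could not be matched to a singly named probe set are not reported here. The rule for named genes was fixed at the same time. It took Jak2, the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap, with places left filled by the smallest p, and up to 4 members of each list with the smallest p. The 7 other called genes, further list members such as H2-Aa, H2-Eb1, Hba-a2 and Csf2rb2, the level taken for absent transcript, and the other probe sets were chosen after their values were seen.

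Alternatives were the replicate number as a block, median centring, filters on dim genes at the median of the probe set means (7.11), the mean of probe sets, probe sets with names in _s_at, _x_at and _a_at (shared between genes or between transcripts of a gene) left out, all probe sets, a trended robust prior, array weights, each array left out, other thresholds, camera with an estimated correlation, and fry. Sex as a covariate, male arrays alone and exact permutation of list means were added after seeing the data. Scripts were tested on simulated data for the comparison of mutant and wild type over 18193 genes, drawn from the real means and spreads with 200 changed genes. Limma recovered 35.8% of genes changed by 0.5 on the log2 scale, 77.6% of those changed by 1 and 100% of those changed by 2, with 7 unchanged genes among 149 called. In a further simulation with independent genes, camera called the shifted list and 0 of 22 others. List members were not correlated in it, so it does not show how often lists are called falsely in these data.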

Results

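Gene expression was measured in haematopoietic stem and progenitor cells of the bone marrow, sorted as lineage-low, Sca1-positive and cKit-high cells (LSK cells), from C57BL/6 mice. The series held 8 arrays, 4 from wild type mice and 4 from mice heterozygous for Jak2V617F, the activated form of the cytokine receptor kinase Jak2 found in myeloproliferative neoplasms. The comparison asked how expression of the mutant kinase at a physiological level changed transcription in the stem and progenitor compartment. Values were deposited log2 intensities, and all changes are mutant minus wild type. The number of arrays limits the precision of each value. Median log2 intensity per array lay between 7.06 and 7.15, and pairwise correlations across probe sets lay between 0.991 and 0.996. The first principal component held 29.6% of the variance and separated the genotypes, with scores from -21.30 to -8.17 in the wild type arrays and from 12.08 to 24.82 in the mutant arrays. The second component held 20.6%.

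Transcript of Jak2 itself was abundant in both genotypes and was not called different. Its log2 intensity was 12.63 ± 0.05 (SD, n = 4) in wild type and 12.43 ± 0.16 (SD, n = 4) in mutant arrays, a difference of -0.20 ± 0.089 (SE) with a limma adjusted p of 0.294. A further Jak2 probe set differed by -0.02. Whether these probe sets read transcript of the mutant allele was not tested, so they do not check the genotype labels.

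Tmem87a, which encodes a multi-pass membrane protein, rose most, by 3.83 ± 0.24 (SE) on the log2 scale or 14.2-fold, from 8.05 ± 0.34 to 11.88 ± 0.46 (SD, n = 4 each; limma adjusted p = 0.000566). Slc1a1, a glutamate and aspartate transporter, rose by at least 2.51 ± 0.23 (SE; limma adjusted p = 0.0054), since its wild type mean of 4.88 was near background. Absent transcript is taken here to read up to 5.37, as the Y-linked gene Eif2s3y read 5.11 to 5.37 in the arrays with female expression. This level differs by probe set, as Y-linked Uty read 3.41 to 4.22 there and Xist read 5.54 to 6.54 in the arrays with male expression. At the level of Xist, further changes given below as sizes would be lower bounds. Among these are Fam3b, Pkp2, Serpinh1, Lrrtm2, Nxnl2, Alas2, Cxcl12, Cxcl2 and Clec1b. Pik3ap1, an adaptor that links receptors to phosphoinositide 3-kinase, rose 3.64-fold, from 8.91 ± 0.13 to 10.78 ± 0.12 (SD, n = 4 each), and had the smallest limma adjusted p, 0.000136. The kinase gene Stk35 rose by 1.65, Gm4951 by 1.59 and Podxl, the sialomucin podocalyxin of progenitor and vascular cells, by 1.49. Smaller rises were those of the sodium and calcium exchanger gene Slc24a3 (1.17), the secreted factor gene Fam3b (1.16), Tmem156 (1.07), Oosp1 (0.97), Rnls (0.80) and Ccdc180 (0.76). The 7 other genes that rose were Cxcr3, a chemokine receptor gene (0.76), Mocs3 (0.75), D730005E14Rik (0.69), C230035I16Rik (0.66), Gm12185 (0.66), Adi1 (0.63) and Clec2m, whose size is not given because it was near background in both genotypes (4.01 and 4.45).

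Wfdc2, which encodes a secreted whey acidic protein domain factor, fell most, by 2.07 ± 0.16 (SE) on the log2 scale, from 9.88 ± 0.37 to 7.81 ± 0.09 (SD, n = 4 each), a 4.19-fold difference with a limma adjusted p of 0.0029. The desmosome gene Dsc2 fell by at least 1.66, its mutant mean of 4.66 being near background. Pkp2, also of desmosomes, fell by 1.44, but was -0.52 with probe sets averaged (limma adjusted p = 0.064) and -0.19 without probe sets whose names end in _s_at, _x_at or _a_at (limma adjusted p = 0.524). Serpinh1, the collagen chaperone of the endoplasmic reticulum, fell by 1.41 and Airn, the noncoding RNA antisense to Igf2r, fell by 1.10. Smaller falls were those of Lrrtm2 (-0.87), Epb41l5 (-0.75), Hdgfl3 (-0.65), Fgfbp3 (-0.60) and Nxnl2 (-0.49), and that of Neb, near background in both genotypes (4.55 and 3.91). Phlpp1, a phosphatase gene that acts on Akt, filled a place among the named falls without passing the threshold (-0.54, limma adjusted p = 0.0553). Other probe sets moved with the chosen one for Serpinh1 (-1.37), Hdgfl3 (-0.65 and -1.07), Epb41l5 (-0.72), Slc1a1 (1.82 or more, from near background) and Lrrtm2 (fell by 0.44 or more, to near background). They were mixed for Airn (-1.03, -0.52 and 0.01), Ccdc180 (0.38 and 0.08) and Pkp2 (-0.62 and -0.19) and differed for Pik3ap1 (0.19). The other probe sets of Dsc2, Stk35, Podxl and Nxnl2, and further ones of Airn, Epb41l5, Lrrtm2, Pkp2 and Slc1a1, were near background in both genotypes and so do not speak for or against the change. Tmem87a, Wfdc2, Gm4951, Slc24a3, Fam3b, Tmem156, Oosp1, Rnls, Neb and Fgfbp3 had 1 probe set each, so no other probe set could be compared. With probe sets averaged, those near background included, the calls of Dsc2 (-0.69, limma adjusted p = 0.096), Epb41l5 (-0.28, 0.096), Lrrtm2 (-0.50, 0.064), Nxnl2 (-0.20, 0.205), Hdgfl3 (-0.79, 0.0514) and Ccdc180 (0.41, 0.0575) also ended.

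**Figure D1:**
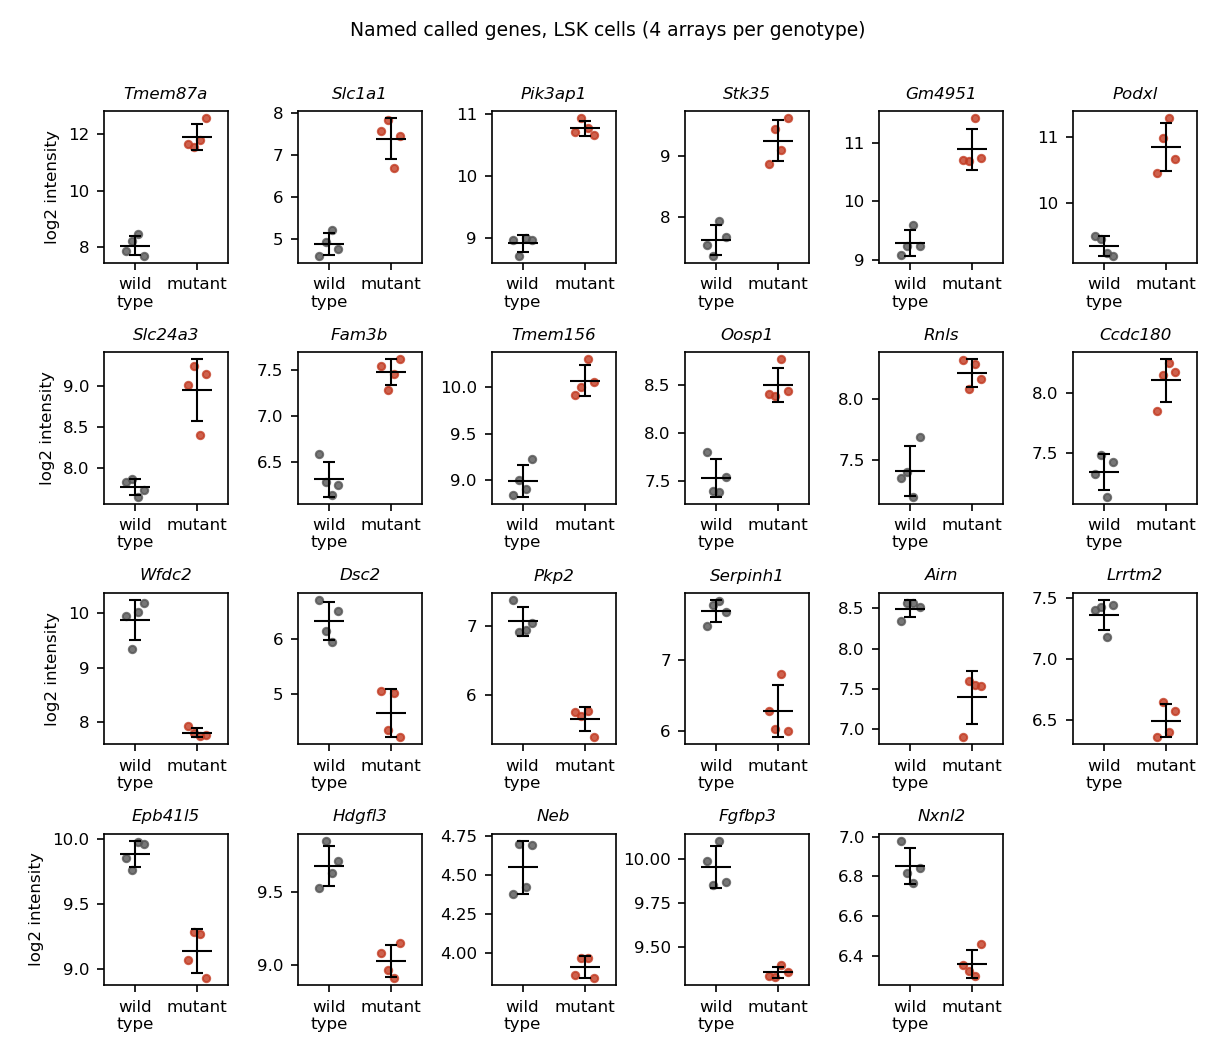
Log2 intensity (vertical axis) of the 23 named genes past the threshold in the 4 wild type (grey) and 4 mutant (red) arrays, 1 point per array, with the mean as a horizontal dash and the SD as bars. In each panel the arrays of the genotypes do not overlap, from Tmem87a (8.05 against 11.88) to Nxnl2 (6.85 against 6.36).

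In all, 30 of 18193 genes passed limma's adjusted threshold, 19 higher and 11 lower in mutant cells, of which 9 and 5 changed at least 2-fold. The 4 mutant arrays lay on a single side of the 4 wild type arrays for each of the 30, and for 10.1% of all genes, against 2.86% by chance. An unadjusted p under 0.05 was found for 3123 genes, 2171 higher and 952 lower. The median change over all genes was 0.05, so list medians near it do not stand apart from genes at large. Camera weighs a list against all other genes, and so can point down where a list mean is above 0. The count of called genes was 47 (37 higher and 10 lower) after median centring, 49 with probe sets averaged, 75 with a trended robust prior, 60 with sex as a covariate and 110 on probe sets, where the majority turned (44 higher and 66 lower). It was 13 without wild type array 2, 16 without wild type array 3, 19 without mutant array 1, 16 without mutant array 2 and 14 without mutant array 4, and 23 without wild type array 1, 37 without wild type array 4 and 40 without mutant array 3.

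Markers of macrophages and dendritic cells lay higher in mutant LSK cells. Of 19 measured members 18 had a change above 0, with a median of 0.50, and the class II antigen genes H2-Ab1 (0.50), H2-Aa (0.96) and H2-Eb1 (1.12) and the invariant chain gene Cd74 (1.18) were among them. Cd68, a lysosomal protein of phagocytes, differed by 0.44 and the iron exporter gene Slc40a1 by 0.74. No member was called over all genes (limma), and 2, H2-Ab1 and Cd68, were called adjusted over the list alone. Camera gave an adjusted p of 0.000826 at its preset correlation, with an adjusted p = 0.864 with an estimated correlation, and the list mean went from 8.10 ± 0.20 to 8.62 ± 0.19 (SD, n = 4 each; exact permutation p = 0.0286, the smallest this design allows, adjusted exact p = 0.282).

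Erythroid genes also lay higher, in 22 of 25 measured members, with a median change of 0.41. The red cell anion exchanger gene Slc4a1 differed by 2.32 ± 0.51 (SE), the beta globin gene Hbb-b2 by 1.67 ± 0.36, the haem synthesis enzyme gene Alas2 by 1.52 ± 0.46 and the erythropoietin receptor gene Epor by 0.55 ± 0.21. The alpha globin gene Hba-a2 stood at 13.20 in wild type and differed by 0.01. The further alpha globin entry, Hba-a1, was near background in both genotypes (4.18 and 4.30). None of these passed over all genes in limma, and Slc4a1 and Hbb-b2 were called adjusted over the list alone. Camera gave an adjusted p of 0.0062 for the list, with an adjusted p = 0.864 with an estimated correlation. The call was lost without wild type array 4 (median 0.27, camera adjusted p = 0.0927) and without mutant array 2 (median 0.27, camera adjusted p = 0.127), and among male arrays, where the median was 0.39 (camera adjusted p = 0.0521). Without mutant array 3 the median was 0.26 (camera adjusted p = 0.0149).

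Among genes of haem synthesis and iron uptake, 4 of 16 measured members were called adjusted over the list alone and 0 over all genes. These were the transferrin receptor gene Tfrc, at 12.72 ± 0.26 in wild type and 13.47 ± 0.07 (SD, n = 4) in mutant cells (0.75, limma adjusted p = 0.0652), Alas2, and the iron transport genes Slc11a2 (0.27) and Steap3 (0.37). The list median was 0.11, and its camera adjusted p was 0.252. The array's transferrin receptor control probe sets also lay higher in all mutant arrays, by 0.63, 0.63 and 0.40. Tfrc was called by limma with median centring (adjusted p = 0.0458), with probe sets averaged (adjusted p = 0.0292) and with a trended robust prior (adjusted p = 0.0218).

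Interferon response genes lay higher in 32 of 33 measured members, by a median of 0.23. Irf7, a transcription factor of the response, differed by 0.66, the antiviral genes Rsad2 and Ifit2 by 0.74 and 0.35, and the immunity-related GTPase gene Igtp by 0.32. No member was called over all genes or adjusted over the list alone (limma), and 8 had an unadjusted p under 0.05. Camera gave an adjusted p of 0.0036, with an adjusted p = 0.864 with an estimated correlation. The call was lost without mutant array 3, in which Rsad2 was highest at 12.49 (median 0.12, camera adjusted p = 0.108), and among male arrays (median 0.12, camera adjusted p = 0.499).

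Haematopoietic stem cell genes were the 1 list called lower by camera, with 14 of 24 measured members below 0 and a median of -0.06. The homeobox genes Hoxa10 (-0.46 ± 0.10, SE) and Hoxa9 (-0.28 ± 0.088), the stem cell transcription factor gene Mecom (-0.34 ± 0.094) and Ndn (-0.42 ± 0.12) had the smallest p. The other 10 members lay above 0, among them Slamf1 (0.72), Vwf (0.39) and Thy1 (0.38), so the list did not move as a whole. An unadjusted limma p under 0.05 was found for 6 members below 0 and for 1, Slamf1, above 0. Hoxa10 was called adjusted over the list alone, and 0 members were called over all genes (limma). Hoxa10 was -0.23 without _s_at, _x_at and _a_at probe sets (limma adjusted p = 0.676) and -0.35 with probe sets averaged, where Mecom was -0.14. Camera gave an adjusted p of 0.0062, with an adjusted p = 0.864 with an estimated correlation, and the list mean differed by -0.07 (exact permutation p = 0.543). Without mutant array 4 the median was 0.01 and the camera adjusted p was 0.0641, without wild type array 1 they were -0.03 and 0.0506, and with dim genes left out -0.06 and 0.0541.

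For these 4 lists the calls rested on the preset correlation. Calls of further lists under alternatives, given below, were also made at the preset correlation. Neither fry nor exact permutation of the list means called any list, and 32 of the 35 splits of the 8 arrays into 4 and 4 called at least 4 lists in camera. Over 19 alternatives the adjusted p ranged from 5.01e-06 to 0.864 for the macrophage and dendritic cell list (camera, fry or exact permutation), from 1.05e-05 to 0.864 for the erythroid and interferon lists and from 0.0012 to 0.864 for the stem cell list. Over all lists, 0 of 473 distinct member genes were called by limma over all genes. Adjusted over the list alone, 19 list entries were called, where a gene in several lists has an entry in each.

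Targets of Stat5 and of cytokines held 2 members called adjusted over the list alone and 0 over all genes. Socs2, a suppressor of cytokine signalling, was at 10.71 ± 0.30 in wild type and 11.44 ± 0.10 (SD, n = 4) in mutant cells, and Id1, an inhibitor of basic helix-loop-helix factors, was at 7.19 ± 0.20 and 7.73 ± 0.06. Both had a limma adjusted p of 0.0819, with all mutant arrays above all wild type arrays, and Socs2 passed with a trended robust prior (limma adjusted p = 0.0393) and was 0.37 with probe sets averaged (limma adjusted p = 0.138). The kinase gene Pim2 differed by 0.36 and Osm by 0.26. Of 18 measured members 11 had a change above 0 and 7 below, with Cish, Pim1 and Ccnd1 each at -0.19 and not called. The list median was 0.17 and the camera adjusted p 0.343. Components of Jak and Stat signalling held 0 of 20 members called over all genes or adjusted over the list alone (limma), and 1, Epor, with an unadjusted p under 0.05. Cbl was at -0.22, Il6st at 0.11 and Csf2rb2 at 0.38 ± 0.30 (SE). Their median was -0.0075 and their mean 0.04, and camera pointed down (adjusted p = 0.343).

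Megakaryocyte and platelet genes had 19 of 23 members above 0 and a median of 0.14 (camera adjusted p = 0.252), with Clec1b at 0.78, the integrin gene Itga2b at 0.46, Gp1bb at 0.78 and Cd9 at 0.23. This list was called by camera with sex as a covariate (median 0.23, adjusted p = 0.0482), among male arrays (median 0.30, adjusted p = 0.0081) and without mutant array 4 (median 0.20, adjusted p = 0.0097). Granulocyte and monocyte genes had a median of 0.20 (camera adjusted p = 0.333), with the granule gene Ltf at 1.41, Hp at 0.73, S100a9 at 0.43 and the transcription factor gene Spi1 at 0.24. They were called by camera with sex as a covariate (median 0.26, adjusted p = 0.0258) and among male arrays (median 0.31, adjusted p = 0.0029). Genes of lymphoid-primed progenitors had a median of -0.06 (camera adjusted p = 0.252), with Lax1 at -0.56, called adjusted over the list alone, and Il12rb1 at 0.29, Cd52 at 0.33 and Ighm at 0.48. Ighm was -0.10 with probe sets averaged. The lymphoid list was called by camera without mutant array 2 (median -0.12, adjusted p = 0.0207). No member of these lists was called over all genes (limma).

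Cell cycle lists were not called over all 8 arrays. G1/S and DNA replication genes had a median of 0.08 (camera adjusted p = 0.511), with the cyclin gene Ccne1 at 0.38, Chaf1b at 0.30, Mcm2 at 0.23 and Rfc4 at 0.20. G2/M and mitosis genes had 27 of 31 members above 0 and a median of 0.11 (camera adjusted p = 0.228), with Plk1 at 0.40, Kif20a at 0.33, Dlgap5 at 0.26 and Cdc20 at 0.23. This list was called without mutant array 2 (median 0.23, camera adjusted p = 6.42e-05) and with dim genes left out (median 0.11, camera adjusted p = 0.0398). Over all 8 arrays its camera adjusted p was 0.885 with an estimated correlation. Cell cycle inhibitors and quiescence genes had a median of -0.0093 and a mean of 0.12, and camera pointed down (adjusted p = 0.272), with Rbl2 at -0.42, Foxo1 at -0.25, Btg2 at 0.74 and Klf2 at 1.19, and were called lower among male arrays (median -0.24, camera adjusted p = 0.0118). Targets of p53 had a median of -0.05 and a mean of 0.02, and camera pointed down (adjusted p = 0.252), with Tnfrsf10b at -0.64, Aen at -0.28 and Plk3 at 0.22. No member of these lists was called, over all genes or adjusted over the list alone (limma).

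Metabolic lists held no member called over all genes or adjusted over the list alone (limma). Their medians, from 0.03 to 0.09, lay near the median change of 0.05 over all genes. Oxidative phosphorylation genes had 25 of 28 members above 0, by a median of 0.07 (camera adjusted p = 0.252), with the complex I genes Ndufv1 at 0.24 and Ndufs1 at 0.18 and the succinate dehydrogenase genes Sdhb at 0.18 and Sdhc at 0.17. They were called with dim genes left out (camera adjusted p = 0.0454). Ribosome biogenesis and Myc target genes had a median of 0.09 (camera adjusted p = 0.511), with Pes1 at 0.20, Nop14 at 0.19, Nop58 at 0.17 and Mybbp1a at 0.17. Cholesterol synthesis genes had a median of 0.06 (camera adjusted p = 0.622), with Mvk at 0.35, Mvd at 0.29, Pmvk at 0.20 and Fdps at 0.20. Both of these were called among male arrays (medians 0.25 and 0.26, camera adjusted p = 0.0016 for each) and without mutant array 3 (medians 0.19 and 0.21, camera adjusted p = 0.0149 for each). Glycolysis and hypoxia genes had a median of 0.03 and a mean of 0.0052, and camera pointed down (adjusted p = 0.738), with Vegfa at -0.95, Slc2a1 at -0.15, Pfkp at 0.24 and Adm near background in both genotypes.

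Of the inflammatory and NF-kB genes, the cytokine genes Il1b and Tnf lay higher in every mutant array. Il1b went from 6.55 ± 0.20 to 7.44 ± 0.30 (SD, n = 4 each; limma adjusted p = 0.0714) and Tnf from 6.64 ± 0.11 to 7.22 ± 0.23 (limma adjusted p = 0.0914), and both were called adjusted over the list alone, with 0 over all genes. Cxcl2 differed by 1.24 and Cd14 by -0.99. The list median was 0.06 (camera adjusted p = 0.815), and Il1b passed with a trended robust prior (limma adjusted p = 0.0445). Immediate early genes, which respond to handling and dissociation of cells, had 20 of 23 members above 0 and a median of 0.51 (camera adjusted p = 0.128), with Egr2 at 1.53 or more (near background in wild type), Junb at 0.81 and Ier2 at 0.78 and no member called over all genes or adjusted over the list alone. They were called without mutant array 3 (median 0.70, camera adjusted p = 0.0071), without wild type array 1 (median 0.59, 0.03) or 3 (median 0.42, 0.0493), and among male arrays (median 0.58, 0.0391).

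Markers of other cells that a sort could carry were not called as lists, apart from the macrophage and dendritic cell genes. Stromal and endothelial genes had a median of -0.07 (camera adjusted p = 0.228), with the sialomucin gene Emcn, also carried by stem cells, at 10.91 ± 0.14 in wild type and 10.07 ± 0.28 (SD, n = 4) in mutant arrays (limma adjusted p = 0.0652) and the chemokine gene Cxcl12 at -1.01. Emcn, Cxcl12, Cdh5 and Cspg4 were called adjusted over the list alone and 0 over all genes, with Cdh5 near background in both genotypes and Cspg4 in wild type, and Emcn passed with sex as a covariate (limma adjusted p = 0.0369), with a trended robust prior (0.0267) and without mutant array 3 (0.0259). Mast cell and basophil genes had a median of 0.20 (camera adjusted p = 0.282), with Cpa3 at 0.55 (limma adjusted p = 0.0909), called adjusted over the list alone, Mcpt8 at 0.58, Ms4a2 at 0.44 and Tpsab1 near background in both genotypes. They were called with sex as a covariate (median 0.53, camera adjusted p = 0.0183) and among male arrays (median 0.45, 0.0016). Mature B, T and NK cell genes had a median of 0.12 (camera adjusted p = 0.511), with Cd3d at 0.52, Gzma at 0.66, Cd8a at 0.25 and Cd4 at -0.45, none called over all genes or adjusted over the list alone.

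**Figure D2:**
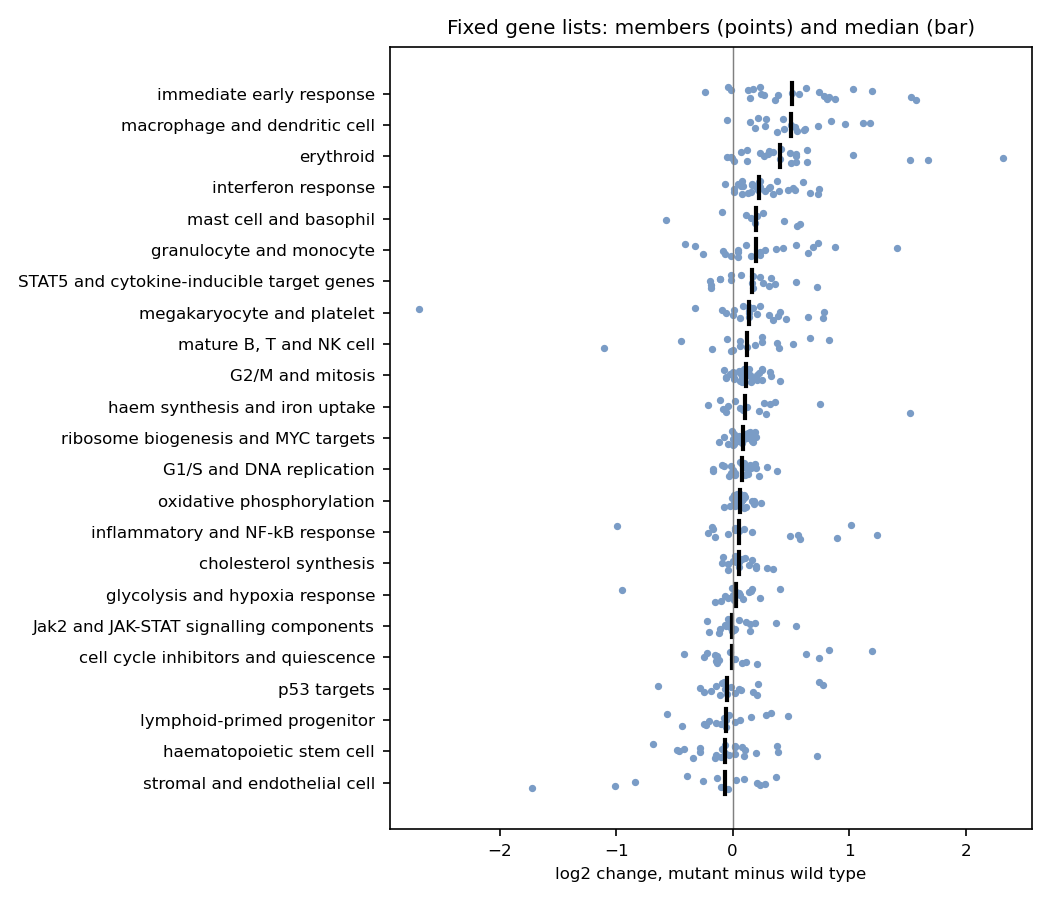
Log2 change, mutant minus wild type (horizontal axis), of each measured member (points) and the median (bar) of the 23 gene lists with at least 5 measured members, ordered by median. Medians run from -0.07 for stromal and endothelial genes to 0.51 for immediate early genes, and the macrophage and dendritic cell list stands at 0.50 and the erythroid list at 0.41.

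Sex of the mice was not in the labels. Xist stood at 13.46 and 13.42 in wild type arrays 1 and 2 and at 13.21 in mutant array 3, and between 5.54 and 6.54 in the other arrays. Eif2s3y, a Y-linked gene, showed the opposite split, with 5.37 in mutant array 3. Read this way, wild type cells came from 2 female and 2 male mice and mutant cells from 1 female and 3 male mice. Kdm5d and Uty, both Y-linked, differed by 0.96 and 1.05 between genotypes, and none of the 4 measured sex-linked genes was called over all genes or adjusted over the list alone (limma). As a sign of RNA handling, the 18S ribosomal control probe set of the middle region was lower in every mutant array, at 12.70 ± 0.33 against 13.49 ± 0.24 (SD, n = 4 each; exact permutation p = 0.0286, adjusted exact p = 0.152). The 3' minus 5' difference was 0.65 in wild type and 0.69 in mutant arrays for Actb (exact permutation p = 0.257) and 0.71 and 0.69 for Gapdh (exact permutation p = 0.914).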

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

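The tests of called genes in the window around Jak2 and of called genes with sex as a covariate were chosen after the result was seen.

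In 21 of 282 groups of 4 arrays, for the named genes and list means, a single array stood far from the other 3, where chance gives about 14.1. Mutant array 3, the 1 mutant array with female expression, gave 10 of these. It stood high for Gm4951 (11.41), Oosp1 (8.76) and Xist (13.21) and low for Ltf (10.06), Slc2a1 (12.68), Eif2s3y (5.37), Uty (4.08) and Kdm5d (3.06), for the glycolysis and hypoxia list mean (11.71) and for the sex-linked list mean (6.43). Those for Xist, Eif2s3y, Uty, Kdm5d and the sex-linked list mean follow from sex and add to the excess over chance.

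Mutant array 1 stood low for Airn (6.90) and for the mean of mature B, T and NK cell genes (6.90). Mutant array 2 stood high for Hoxa9 (12.94) and Cpa3 (11.68) and low for Kif20a (11.45), and mutant array 4 stood low for Tpsab1 (4.47). Among wild type arrays, array 1 stood high for Icam4 (9.80), array 2 low for Pik3ap1 (8.71), array 3 low for Lrrtm2 (7.18) and Chaf1b (12.18), and array 4 high for Kif20a (11.72).

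Control probe sets, which the comparison of genes leaves out, carried a difference for the transferrin receptor. Their mutant means were 10.34, 6.35 and 8.47, against 9.70, 5.71 and 8.07 in wild type arrays, with every mutant array above every wild type array. The genotypes did not overlap for 12 of the 64 control probe sets, where chance gives about 1.83, each with an adjusted exact p of 0.152. Several of the 12 read the same transcript, so they are not all separate results. Of the 12, 6 were for spiked bacterial RNA, which the cells do not carry. The 3 lower in mutant arrays (-0.19, -0.11 and -0.11) all read the same spike, bioD. The 3 higher were near background in both genotypes, so their sizes are not given. Their means were 4.58, 4.26 and 3.66 in wild type and 4.71, 4.42 and 3.94 in mutant arrays. With bioD lower in every mutant array, a technical difference that runs with genotype is not excluded. In a test on all probe sets 37 called probe sets had no single gene name, 4 higher and 33 lower, and these are not named here.

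The 30 called genes were weighed against chance, sex and the origin of the mutant chromosome. Of the 35 splits of the 8 arrays, 1 called as many genes, the real split with 30, and the highest of the others called 1. That is the smallest share that 35 splits allow. The other splits mix the genotypes, which widens the spread within their groups, so few calls were likely there. Chance is thus made less likely but is not excluded. With sex as a covariate 26 of the 30, 86.7% (95% interval 69.3 to 96.2), stayed called in the same direction, which argues against unequal sexes as the cause of most of them. Genes called near Jak2 may come from a chromosome segment carried with the altered allele. Of the 30, 5 lay within 200 measured genes of Jak2 (Fisher's exact one-sided p = 0.000473). These were Oosp1, Slc1a1, Rnls, Fgfbp3 and Pik3ap1, at -77, -8, 28, 57 and 102 measured genes from it. The window is wide, with 400 of the 609 measured genes of chromosome 19, and took in all 5 called genes of that chromosome. Over whole chromosomes the adjusted p (Fisher's exact) was 0.0642 for chromosome 19 and 0.268 for chromosome 2, with 6 called. Uncalled genes in the window had an unadjusted p under 0.05 at an odds ratio of 1.01 (95% interval 0.765 to 1.32). Called genes were left out of that test, so it could miss a segment that changed few genes, which leaves this open. Sequence differences under single probe sets also stay open. Only 15 of the 30 called genes had another probe set. Of the brighter other probe sets 71.4%, 5 of 7, moved the same way by 0.5 or more of the change, short of the bound set against this explanation. Of all 27, 8 did, but the 27 include probe sets near background that do not speak for or against a change. A direct effect of the mutant kinase was not tested apart from these explanations.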

How the results depend on the processing

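Sex as a covariate, male arrays alone and exact permutation of list means were chosen after seeing the data.

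All 30 called genes kept their direction in every fit across genes that tested them. For fits on fewer arrays this was fixed in advance, since the arrays of the genotypes did not overlap for any of the 30. The replicate block, the filters and the trended robust prior reuse the same change, so the direction could not turn there either. Tmem87a, Pik3ap1 and Wfdc2 stayed called in each of 18 alternatives (highest limma adjusted p 0.0455, 0.0298 and 0.044), and Nxnl2 in 1 of 16. The call was lost in 12 of 16 for Neb, 10 of 16 for Dsc2, 6 of 16 for Serpinh1, 11 of 18 for Ccdc180, 10 of 18 for Epb41l5 and Hdgfl3, 9 of 18 for Airn and Rnls, 8 of 18 for Slc24a3 and Fgfbp3, 7 of 18 for Oosp1, 5 of 18 for Podxl, 4 of 17 for Lrrtm2 and 1 or 2 for Stk35, Tmem156, Pkp2, Fam3b, Gm4951 and Slc1a1. The count of 30 (19 higher, 11 lower) became 47 (37 higher) with median centring, 49 (38 higher) with probe sets averaged, 75 (47 and 28) with a trended robust prior, 60 (39 and 21) with sex as a covariate, 110 probe sets (44 and 66), 14 (9 and 5) at 2-fold and 199 (135 and 64) at an adjusted p under 0.1. With the filter on the mean, 7 were lower. Male arrays alone called 22, sharing 10 with the 30. Leaving out each array gave 13 to 40 (8 to 28 higher, 3 to 12 lower). The fits with fewer arrays have less power, yet 2 of the 8 called more genes, and the cause of the shifts was not tested. With the replicate number as a block the count was 8 (4 and 4), 5 shared with the 30, and 4 lists were called; the numbers do not pair the mice (correlations -0.02, -0.22, -0.06 and 0.10, with 1 of 4 mutant arrays correlating best with its own number). The 4 called lists became 7 with sex as a covariate, 9 with male arrays alone, 0 with an estimated correlation, 0 with fry and 0 with exact permutation, and 3 to 6 when leaving out each array. No scanner files were used here, so signal over background was not measured.

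Over their alternatives the adjusted p (camera, fry or exact permutation) ranged from 0.0081 to 0.933 for megakaryocyte, 0.0029 to 0.933 for granulocyte, 0.0207 to 0.876 for lymphoid, 6.42e-05 to 0.965 for G2/M, 0.0118 to 0.910 for cell cycle inhibitors, 0.0454 to 0.864 for oxidative phosphorylation, 0.0016 to 0.970 for ribosome biogenesis, 0.0016 to 0.987 for cholesterol, 0.0071 to 0.864 for immediate early and 0.0016 to 0.864 for mast cell genes. The limma adjusted p ranged from 0.0218 to 0.146 for Tfrc, 0.0393 to 0.190 for Socs2, 0.0445 to 0.170 for Il1b and 0.0259 to 0.173 for Emcn. Among named genes not called, Ighm was -0.10 with probe sets averaged and -0.042 without _s_at, _x_at and _a_at probe sets. Sex as a covariate gave Uty -0.040, Xist 0.29 and Kdm5d -0.50, and male arrays alone gave -0.21, 0.58 and -0.23. Kdm5d ranged from -0.24 to 2.53 leaving out each array. For lists not called the direction of the test turned as follows, with the medians given. The median itself changed sign, among these, for G1/S with male arrays and for inflammatory genes with male arrays and without wild type array 2 or mutant array 2. Sex as a covariate gave -0.000182 for Jak and Stat components and 0.074 for G1/S. Fry and exact permutation pointed up at -0.0075 for Jak and Stat components and 0.032 for glycolysis, and exact permutation at -0.0093 for cell cycle inhibitors and -0.049 for p53 targets. Leaving out _s_at, _x_at and _a_at probe sets gave 0.030 for Stat5 targets and 0.024 for inflammatory genes. Male arrays gave -0.0070 for G1/S, 0.017 for G2/M, 0.096 for glycolysis and -0.000683 for inflammatory genes. The filter on the mean gave 0.024 for glycolysis and 0.022 for inflammatory genes, and median centring 0.10 for the latter. Leaving out each array turned the camera direction of 5 lists for some arrays, with medians of 0.017 to 0.12 for G1/S, 0.027 to 0.19 for ribosome biogenesis, 8.33e-06 to 0.069 for glycolysis, 0.0047 to 0.21 for cholesterol and -0.019 to 0.19 for inflammatory genes. The cause was not tested.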

Other observations

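The baseline condition on Hba-a2 was chosen after the result was seen, as were the Hba-a2 test itself and the test of the macrophage list without the class II genes and Cd74, and the genes of the Hox, class II and erythroid groups outside the fixed lists were chosen after the fixed lists were seen.

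Homeobox genes beyond Hoxa9 and Hoxa10 lay lower in mutant cells in part. Of 14 further Hoxa and Hoxb genes 6 were above 0, with a median of -0.15, and Hoxb6, Hoxb2 (-0.50) and Hoxa3 (-0.34) had the lowest p below 0, with Hoxb6 lower by at least the -0.64 measured, its mutant mean being near background, while Hoxb7, near background in both genotypes, and Hoxb4 (0.01) were above 0. None was called over all genes (limma). The hypothesis that the family is lower gave a camera p of 0.00588, an estimated correlation p of 0.0555 and an exact permutation p of 0.0857 for the mean shift of -0.15.

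Genes of class II antigen presentation outside the fixed lists went both ways. The transactivator gene Ciita was at 0.60 and the costimulatory receptor gene Cd40 at 0.50, each with all mutant arrays above all wild type arrays, H2-DMb2 at 0.44 and H2-Ob at -0.39. None of the 9 was called over all genes (limma). Among erythroid genes outside the lists, 19 of 23 were above 0, with Samd14 at 0.58 (limma adjusted p = 0.0652), Tfr2 at 0.21 and Atp1b2 at 0.94.

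The gene lists as a whole were weighed against chance. Of the 35 splits, 32 called at least 4 lists, as the real split did, and the highest of the others called 16, so chance cannot be excluded for the list calls, and what gave the many calls in other splits was not tested.

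Higher erythroid values may reflect maturing red cells carried through the sort, most of which the lineage-low and cKit-high gates would remove, or erythroid expression within LSK cells. The change of Hba-a2, 0.014 (95% interval -0.15 to 0.18), lay below 0.5 of the median of Slc4a1, Alas2 and Rhag (1.52), which met the bound first set against carried red cells. That bound was then set aside, because Hba-a2 stood at 13.20 in wild type, above 94.4% of genes, where a small share of red cells could be hidden, so the explanation stays open. Erythroid genes outside the lists gave a camera p of 0.0363 upward, an estimated correlation p of 0.405 and an exact permutation p of 0.20.

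Higher macrophage and dendritic cell values may come from carried macrophages or from class II expression in LSK cells. Without the class II genes and Cd74 the list kept a median of 0.43 (14 of 15 above 0, camera p = 0.0015, estimated correlation p = 0.148), below 0.5 of the class II median of 1.04, so the test of carried macrophages did not decide. Class II presentation genes outside the lists gave a camera p of 0.186 and a mean shift of 0.18 (95% interval -0.11 to 0.46), which leaves that explanation open too. The lineage-low and cKit-high gates would remove most mature macrophages, and mean levels in wild type and mutant arrays were 6.41 and 6.79 for C1qa, 8.57 and 9.13 for C1qb and 11.94 and 13.11 for Cd74.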
